A study of Rattus norvegicus with 83 samples.

How the data were processed

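Per the labels, total RNA came from male Sprague-Dawley rats 3 months of age that had received saline, amphetamine or heating from outside, and tissue was taken 3 h or 1 day later. For each of the 83 samples 500 ng of RNA was labelled with the single dye Cy3 and hybridized to a rat array of 45220 spots, among them 43379 gene spots for 41012 gene probes under 35752 gene names. The doses and the temperatures reached are not given in the sources used here. The intensity values are spot and local background brightness per the file headers, in tables of the GenePix format whose software version is not given in the sources used here. Per the file headers, the same tables hold the percent of saturated pixels of each spot, and other columns hold flags and positions. The deposited series table holds intensity values that equal the median spot brightness for 100% of spots, with medians of 50.0 to 178.0 per array, so it carries no scaling between arrays.

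Groups were formed from the labels by tissue, treatment and time, which gave 15 groups. A parietal cortex sample of rat 29 is called 3 h by most of its labels and 3 day by 1 of them, and was grouped at 3 h. The hyperthermia sample of rat 12 at 3 h in PC was not analysed here. The comparisons, tests, filters, gene lists, rule for named genes and first set of alternatives were chosen before the data were examined. They had been written for files of another scanner software, so equivalents in the GenePix columns were used. No pair of arrays was identical, and each of the 83 arrays was closest to an array of its own tissue.

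Background was removed with the normexp model (limma 3.58.1 in R 4.3.3, offset 50) from the mean spot brightness minus the median local background, values were taken to log2, and each array was shifted by its 75th percentile. Spots with a flag at or below -75 were left out, 775 over all arrays. Some spots lay far below their local background, and the model fitted on all spots had an estimated mean below -20 on 15 arrays and as low as -476. The model was therefore fitted without spots lying over 20 below their background, 0 to 42 per array, which gave means from -12.9 to 1.82. This step was chosen after the counts with all spots had been seen, because of the parameters and before its own counts were made. Capping the background at 3 median absolute deviations above its median, 199 to 2493 spots per array, was tried before it, on its parameters alone, and is an alternative, with means from -8.87 to 1.88.

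A spot was well above background where its median brightness exceeded the local background by over 2.6 background standard deviations, and saturated where over 50% of its pixels were. The arrays had 37.08% to 86.88% of gene spots well above background (median 46.62%) and 9.0 to 72.0 saturated spots. A probe was tested where it was well above background on at least 75% of the arrays of a group in the fit, with the brightest probe for each gene name. Symbols came from the reference table of rat genes, which matched 19401 probes, 11054 by accession, 4998 by symbol and 3349 by synonym, while 21611 had no match and 19523 probes have a symbol from either source. Folds against a group with no array above background are bounds against the lowest level of a probe well above background on each array, and folds of saturated probes are lower bounds.

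Linear models were fitted with limma with group means, empirical Bayes moderation and Benjamini-Hochberg adjustment, at a threshold of 0.05. The saline comparison of tissues used the 12 saline arrays, each tissue's treatments its own 5 groups, and the differences between tissues all 83 arrays. A feature is MAV-enriched where the adjusted p passes and the log2 difference is at least 2 against both regions. Lists of genes, 27 in number, were tested with camera at a preset correlation of 0.01, and with an estimated correlation, where at least 3 members were measured. Members were also adjusted over the list alone. For amphetamine against saline, the MAV-enriched set came from 2 saline rats and its change from the other 2. Named genes are the 10 highest and 10 lowest changes with a symbol, past the threshold and without overlap between groups, for the tissue comparisons of MAV and for amphetamine at 3 h, and 5 and 5 elsewhere. Up to 4 members of a described list with the smallest adjusted p were named too, restricted to members past the threshold after a first table had been seen. The 15 MAV-enriched genes highest in MAV level were named too, but not every named gene is reported here.

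Slides were inferred from the geometry of the scans, which gave 27. The 2 scan runs were inferred from 4 features of each slide, namely scan offset, the levels of the positive and negative control spots, and the first component of expression within groups. Versions with 5 and 3 features were tried first, and the choice was made after seeing where 2 slides of PC fell, so the runs are an inference from the data. Tissues of the same rat deviated together from their group means, with a median correlation of 0.29 for MAV and STR, 0.18 for MAV and PC and 0.34 for STR and PC, against -0.05, -0.03 and -0.06 for different rats of a group. It was over 0.1 in 24 of 28, 19 of 27 and 26 of 27 rats. The rat numbers of the labels are the source of the pairing, and the rat was a block in an alternative. Estimated correlations within blocks were 0.159, 0.319 and 0.312 for slides in MAV, STR and PC, and 0.239 for rats.

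Alternatives were quantile scaling, the deposited values, no filter on dim probes, the mean of probes, blocks for rat, slide and run, fits on the 2 groups compared, and leaving out each array in turn. The planned quantile scalings with and without normexp came to the same setting here. Run, slide as a fixed block, fits within a run, the background versions and leaving out 3 doubtful arrays were added after the data were seen. The doubtful arrays are MAV AMPH 1 day rat 7 and STR EIH 1 day rat 21, with high non-specific signal, and PC AMPH 1 day rat 30, with the most spots not found. The file of STR AMPH 3 h rat 26 lacks the end of 1 control spot. The scripts were tested on simulated data with 200 changed genes: for amphetamine at 3 h in MAV (17098 features) 22.4% of changes of 0.5, 91.0% of changes of 1 and 97.0% of changes of 2 on the log2 scale were recovered, with 5 calls among unchanged features. For the difference between MAV and STR (19303 features) these were 11.9%, 71.6% and 93.9%. Figures and text tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.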

Results

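The series holds 1-colour microarrays of RNA from 3 tissues of male rats 3 months of age: the meninges with their associated vasculature (MAV), the striatum (STR) and the parietal cortex (PC). Rats had received saline, environmental hyperthermia (EIH, heating of the animal from outside) or amphetamine (AMPH), and tissue was taken at 3 h or 1 day. In each tissue 4 arrays came from saline rats at 3 h, 7 from amphetamine rats at 3 h, 5 from hyperthermia rats at 1 day and 8 from amphetamine rats at 1 day. Hyperthermia at 3 h had 4 arrays in MAV and STR and 3 in PC. Rat numbers come from the labels, and tissues of the same number come from 1 animal. Each of the 83 arrays carried 43379 gene spots, whose median brightness per array ran from 51.0 to 185.0, with a median of 68.0 over arrays, against a local background of 38.0 to 44.0. Between 37.08% and 86.88% of gene spots lay well above background. The number of arrays limits the precision. No level at 1 day after saline was measured, so a comparison of a 1-day group with saline also compares different times.

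Levels are log2 values relative to the 75th percentile of each array, changes are log2 differences with their standard error (SE), and calls are made by limma at an adjusted p under 0.05. Slides of each tissue fell into 2 scan runs, inferred per tissue from scans and expression values. Run 1 of a tissue need not be run 1 of another. All 4 saline arrays of MAV and of PC lay in run 1, and all 4 of STR in run 2. Hyperthermia arrays at 3 h all lay in run 1. Counts with the run as a block are therefore given too, and counts within a run where 1 run held enough arrays of both groups. Genes called highest or lowest are those whose groups did not overlap. With the background model fitted on every spot, as first planned, each nonzero count for a treated group fell by over 1.5 times. Amphetamine at 3 h in MAV gave 647 in place of 2611. Where leaving out 1 array moved a count by over 1.5 times, the rats are named with the counts in the same order. Of 100 mixed splits of the arrays, 11 gave as many camera list calls as the real 27 for amphetamine at 3 h. Camera p-values are given with the more cautious ones from an estimated correlation.

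The first question of the series is which genes mark the meninges and their vessels against brain tissue. In saline rats MAV held far more of the transcripts of the choroid plexus, of leptomeningeal fibroblasts and of smooth muscle than either brain region. Ttr, the transthyretin carrier of thyroid hormone and retinol made by choroid plexus epithelium, reached 7.00 ± 0.99 (SD, n = 4) in MAV and was 163-fold higher than in STR, where 2 of 4 arrays measured it, and 317-fold higher than in PC, where 1 of 4 did. With 3 of 4 MAV arrays saturated, neither its level nor these folds are exact. Igfbp2, an insulin-like growth factor binding protein, was 97.1-fold higher than in STR (6.60 ± 0.13, adjusted p = 7.68e-13), with 1 of 4 STR arrays above background, and 40.3-fold higher than in PC. The fibrillar collagen gene Col3a1 was 90.5-fold and 63.6-fold higher (2 of 4 STR arrays above background), the proteoglycan gene Ogn 103-fold and 58.7-fold, and Tnnt2, a troponin of striated muscle, at least 116-fold and 74.2-fold, against STR and PC in that order. In the other direction Tac1, the substance P precursor of striatal neurons, was 71.8-fold lower in MAV than in STR, and Hpca, a neuronal calcium sensor, was 44.1-fold lower than in PC.

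Several lists of genes fixed before the data were examined were mostly higher in MAV. All 18 measured leptomeningeal fibroblast markers were higher in MAV, with a median log2 difference of 4.87 against STR (camera adjusted p = 1.57e-10, and 0.177 with estimated correlation) and 4.75 against PC (camera adjusted p = 5.1e-09, and 0.207 with estimated correlation). Examples are Col3a1 and Dcn (46.3-fold and 44.5-fold), the latter above background on 2 of 4 STR and 3 of 4 PC arrays. Extracellular matrix genes were higher in 18 of 19 against STR (camera adjusted p = 3.13e-09, and 0.177 with estimated correlation). Against PC they were higher in 19 of 19 (camera adjusted p = 4.18e-08, and 0.207 with estimated correlation), with Col1a1 54.1-fold and 36.3-fold higher. Of 16 retinoid and growth factor genes of the meninges 15 were higher than in STR (camera adjusted p = 1.37e-07, and 0.177 with estimated correlation). All 16 were higher than in PC (camera adjusted p = 5.2e-07, and 0.207 with estimated correlation), among them Crabp2, a retinoic acid binding protein (26.7-fold and 57.2-fold). Of 10 choroid plexus markers 9 and 10 were higher (camera adjusted p = 0.00694, and 0.496 with estimated correlation for STR, and camera adjusted p = 0.00909, and 0.459 with estimated correlation for PC), with the water channel gene Aqp1 at least 15.4-fold and at least 19.1-fold higher. Adjusted over the list alone, these lists held 18, 18, 15 and 10 members past the threshold against STR and 18, 19, 16 and 10 against PC.

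Most vessel and immune genes on the fixed lists were higher in MAV as well. Of 16 endothelial markers 12 were higher than in STR and 13 than in PC (camera adjusted p = 0.00314, and 0.23 with estimated correlation for STR, and camera adjusted p = 0.0025, and 0.21 with estimated correlation for PC), with Vwf, the von Willebrand factor, 9.78-fold and 11.5-fold higher and Slco1a4, an organic anion transporter of brain vessels, 6.68-fold and 5.69-fold. Of 12 mural cell markers 10 and 10 were higher (camera adjusted p = 0.00278, and 0.371 with estimated correlation for STR, and camera adjusted p = 0.0065, and 0.368 with estimated correlation for PC), led in fold by Tagln (23.6-fold and 35.2-fold). Tight junction and barrier transporter genes were higher in 16 and 17 of 19 (camera adjusted p = 9e-05, and 0.177 with estimated correlation for STR, and camera adjusted p = 8.76e-05, and 0.207 with estimated correlation for PC), with the GABA transporter gene Slc6a13 42.2-fold and 45.2-fold higher. Microglia and macrophage markers were higher in 8 and 9 of 12 (camera adjusted p = 0.00513, and 0.243 with estimated correlation for STR, and camera adjusted p = 0.00239, and 0.21 with estimated correlation for PC), with the mannose receptor gene Mrc1 20.1-fold and 22.2-fold higher (1 of 4 STR and 2 of 4 PC arrays above background). Interferon-responsive genes were higher in all 15 (camera adjusted p = 1.14e-05, and 0.183 with estimated correlation for STR, and camera adjusted p = 1.67e-05, and 0.21 with estimated correlation for PC). Neuron markers were lower in all 14 (camera adjusted p = 1.07e-05, and 0.177 with estimated correlation for STR, and camera adjusted p = 9.18e-07, and 0.207 with estimated correlation for PC), for example Grin1, an NMDA receptor subunit gene, 17-fold and 15-fold lower. Oligodendrocyte markers were lower in all 8 (camera adjusted p = 0.000425, and 0.243 with estimated correlation for STR, and camera adjusted p = 0.00122, and 0.266 with estimated correlation for PC), with the myelin gene Mbp 36.2-fold and 21.1-fold lower.

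In all, 13832 of 17968 features differed between MAV and STR (6424 higher in MAV) and 14225 between MAV and PC (7312 higher). A set of 683 features with 485 gene symbols passed the threshold and was at least 2 log2 units higher in MAV than in both regions, here called MAV-enriched. The 15 genes in it whose probes had the highest signal in MAV were Ptgds, Hba-a3, Igf2, Slc13a3, Timp2, Fmod, Ttr, Tpm2, Ogn, Bgn, Ptrf, Nnat, B2m, Hbb-b1 and Vim. Probes differ in brightness and several are saturated, so this order does not rank transcripts by amount. The prostaglandin D synthase gene Ptgds had a level of 7.57 ± 0.10 (SD, n = 4) with all 4 MAV arrays saturated, so its differences are bounds, at least 6.97-fold over STR and at least 4.29-fold over PC. The same holds for the hemoglobin gene Hba-a3 (at least 5.3-fold and at least 5.33-fold) and the growth factor gene Igf2 (at least 32-fold and at least 27-fold). Vim, an intermediate filament gene, was 33.8-fold and 37.7-fold higher, the proteoglycan gene Fmod 81.7-fold and 38.7-fold, and the dicarboxylate transporter gene Slc13a3 27.7-fold and 14.8-fold. The set held all 18 leptomeningeal markers, all 4 erythroid markers, 13 of 19 extracellular matrix genes, 12 of 16 retinoid and growth factor genes, 6 of 10 choroid plexus markers, 8 of 19 barrier genes, 5 of 12 microglia and macrophage markers and 4 of 16 endothelial markers. A fit over all 83 arrays with run as a block called 12319 features against STR, 13195 against PC and 720 MAV-enriched ones.

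Between the brain regions, STR was marked by genes of striatal projection neurons. Rgs9, a regulator of G protein signalling, was 71.7-fold higher in STR (6.16 ± 0.22, adjusted p = 7.19e-10), the adenosine receptor gene Adora2a 48.9-fold, Tac1 30.6-fold and the enkephalin precursor gene Penk 20.8-fold. All 11 measured markers of striatal projection neurons were higher (camera adjusted p = 7.08e-13, and 0.00238 with estimated correlation, 11 adjusted over the list alone). PC was higher in 7 of 8 cortical excitatory neuron markers (camera adjusted p = 9.83e-08, and 0.0267 with estimated correlation, 7 adjusted over the list alone), with the neuronal transcription factor gene Neurod2 7.32-fold higher than in STR. The neuropeptide genes Vip (9.42-fold) and Grp (9.99-fold, with 2 of 4 STR arrays above background) and Nrn1 (at least 7.66-fold) were also higher in PC. Of 17968 features 8196 differed, 4872 of them higher in STR. Tissue and run coincide in these saline arrays, and a fit over all 83 arrays with run as a block called 3902, 1553 of them higher in STR.

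At 3 h after amphetamine heat shock, endoplasmic reticulum stress and inflammatory genes rose in MAV. Hspb1, a small heat shock protein gene, was 17.7-fold higher than in saline rats (log2 4.14 ± 0.36, adjusted p = 6.63e-08), with a level of 6.79 ± 0.48 (SD, n = 7) against 2.64 ± 0.60 (SD, n = 4). The nuclear receptor gene Nr4a1 was 12.8-fold higher (3.67 ± 0.59, adjusted p = 0.000138). Fst, which encodes the activin antagonist follistatin, was 11.1-fold higher with 3 of 4 saline arrays above background, the metallothionein gene Mt1 10.2-fold, and the transcription factor gene Cebpd 9.72-fold (1 of 7 amphetamine arrays saturated). The lectin genes Reg3b and Reg3a, not above background in saline rats, were at least 13.2-fold and at least 12.6-fold higher. Hsph1 (9.15-fold), Gadd45g (8.69-fold) and Apold1 (8.4-fold) complete the 10 with the highest change among genes whose groups did not overlap. The groups of Hspa1a overlapped, and its change was 3.97 ± 0.75 (adjusted p = 0.000672, 1 of 7 amphetamine arrays saturated). Among the 10 lowest by the same rule were Degs2 (3.77-fold lower, 6 of 7 amphetamine arrays above background), the microglial purinergic receptor gene P2ry12 (3.07-fold), the cold-inducible RNA-binding protein gene Cirbp (2.95-fold), the endothelial transcription factor gene Sox18 (2.69-fold), Trem2 (2.69-fold) and the tight junction gene Ocln (2.65-fold). Ada, Pdgfrl, Acat1 and Gng8 were 2.91-fold, 2.73-fold, 2.72-fold and 2.64-fold lower.

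Of 20 heat shock and chaperone genes 16 rose (camera adjusted p = 5.59e-20, and 0.0406 with estimated correlation), among them the mitochondrial chaperonin genes Hspd1 (5.62-fold) and Hspe1 (4.18-fold). Endoplasmic reticulum stress genes rose in 16 of 21 (camera adjusted p = 5.09e-15, and 0.0406 with estimated correlation), for example Hspa5, which encodes the chaperone BiP (2.78-fold), and Creld2 (3.23-fold). Of 21 immediate early genes 15 rose (camera adjusted p = 2.06e-13, and 0.0628 with estimated correlation), with Nr4a3 7.6-fold (3 of 4 saline arrays above background) and Junb 5.45-fold higher. Inflammatory genes rose in 11 of 18 (camera adjusted p = 3.53e-08, and 0.0409 with estimated correlation), led in fold by the chemokine gene Cxcl1 (7.5-fold), with Cxcl2 at least 3.84-fold and Socs3 2.1-fold higher. Above background lay 2 of 4 saline arrays for Cxcl1, 1 of 4 for Socs3, and 6 of 7 amphetamine arrays for Cxcl2. Glucocorticoid-responsive genes rose in 8 of 14 (camera adjusted p = 7.64e-07, and 0.161 with estimated correlation). Of the oxidative stress genes 4 of 11 rose (camera adjusted p = 0.0126, and 0.312 with estimated correlation), with Hmox1, the inducible heme oxygenase, 7.03-fold higher. Tight junction and barrier transporter genes fell in 7 of 19 and rose in 1 (camera adjusted p = 0.00663, and 0.168 with estimated correlation), with Ocln, Slco1a4 (2.57-fold lower) and the efflux pump gene Abcg2 (1.81-fold lower) among them. Interferon-responsive genes fell in 3 of 15 and rose in 1 (camera adjusted p = 0.0456, and 0.628 with estimated correlation). Hypoxia-responsive genes rose in 3 of 11 (camera adjusted p = 0.00399, and 0.158 with estimated correlation). When adjusted over the list alone, 18 heat shock, 19 endoplasmic reticulum, 16 immediate early, 14 inflammatory, 9 glucocorticoid, 4 oxidative, 10 barrier, 5 interferon and 6 hypoxia genes passed.

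Of 17098 features 2611 changed, 1073 higher and 1538 lower. Blocked by run 2950 passed, by slide 2266, and within run 1, with 3 amphetamine arrays, 1550. The count was 1642 without saline rat 3.

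Hyperthermia without the drug gave a heat shock response in MAV at 3 h. Hspa1a, the inducible Hsp70 gene, was 62.6-fold higher than in saline rats (log2 5.97 ± 0.84, adjusted p = 0.000104), with levels of 7.19 ± 0.66 (SD, n = 4) and 1.23 ± 2.45 (SD, n = 4). Since 2 of 4 hyperthermia arrays were saturated, this size is not exact. Hmox1 was 20.7-fold higher, Hspb1 14.3-fold, Nr4a1 12.2-fold and Hsph1 11.4-fold, while Cirbp was 3.09-fold lower, Gng8 2.43-fold and Exoc7 2.3-fold. Of 20 heat shock genes 19 rose (camera adjusted p = 1.04e-40, and 0.00232 with estimated correlation). Immediate early genes rose in 11 of 21 (camera adjusted p = 5.72e-19, and 0.0319 with estimated correlation), with Atf3 8.71-fold and Fos 7.99-fold higher. Interferon-responsive genes fell in 4 of 15 (camera adjusted p = 8.1e-07, and 0.0998 with estimated correlation), with Rsad2 2.52-fold and Oas1a 2.27-fold lower. Endoplasmic reticulum stress genes rose in 6 of 21 (camera adjusted p = 4.84e-11, and 0.0712 with estimated correlation). Neuron markers had a median of 0.65 and rose in 1 of 12, Gad2 (camera adjusted p = 7.1e-05, and 0.268 with estimated correlation). Past the threshold adjusted over the list alone were 20 heat shock, 15 immediate early, 8 interferon, 12 endoplasmic reticulum and 1 neuron genes.

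Of 17098 features 492 changed, 239 higher and 253 lower. Blocked by run, 817 passed, blocked by slide 759, and within run 1 alone 434. The count was 302, 283, 188 or 303 without saline rat 1, 2, 3 or 4, and 211, 112, 260 or 1054 without EIH 3 h rat 12, 13, 14 or 24.

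Set against hyperthermia at the same time, Fst in MAV was 5.36-fold higher after amphetamine (2.42 ± 0.41, adjusted p = 0.00686), the hyaluronan synthase gene Has1 4.36-fold, the decoy receptor gene Il1r2 3.66-fold, the endotoxin co-receptor gene Cd14 3.44-fold and the protease gene Adamts9 2.95-fold. Nefm, a neurofilament gene, was 2.12-fold lower and Hmx3 2.11-fold lower. Heat shock genes were lower than after hyperthermia in 3 of 20 (camera adjusted p = 0.00511, and 0.712 with estimated correlation, 5 adjusted over the list alone), namely Dnajb1 (4.27-fold), Dnajb4 (2.48-fold) and Hspa1b (at least 1.71-fold, 3 of 4 hyperthermia arrays above background). Inflammatory genes had a median of 0.43 (camera adjusted p = 9.64e-05, and 0.273 with estimated correlation, 2 adjusted over the list alone), with Il1rn, the interleukin-1 receptor antagonist gene, 2.3-fold higher. Of 17098 features 62 differed, 36 higher after amphetamine. The run-blocked count was 98, of which 42 were higher, the slide-blocked one 10 and that within run 1 was 15. The count was 33, 14 or 10 without EIH 3 h rat 12, 13 or 14, and 19, 32, 26, 309, 14 or 15 without AMPH 3 h rat 5, 6, 18, 26, 27 or 29.

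At 1 day after amphetamine Reg3b in MAV was at least 23.3-fold higher than in saline rats (4.59 ± 0.84, adjusted p = 0.00872), the metalloprotease inhibitor gene Timp1 3.93-fold with 1 of 8 amphetamine arrays saturated, the lipid metabolism gene Angptl4 3.67-fold, the lipopolysaccharide binding protein gene Lbp 3.67-fold with 7 of 8 amphetamine arrays above background, and Nnmt 2.94-fold. The transporter gene Slc47a1 (2.45-fold, 7 of 8 amphetamine arrays above background), Alpl (2.31-fold), the fatty acid desaturase gene Fads1 (2.02-fold) and Defb1 (1.97-fold) were lower. Interferon-responsive genes fell in 2 of 15, Rsad2 (2.37-fold) and Mx2 (1.69-fold, 6 of 8 amphetamine arrays above background) (camera adjusted p = 8.2e-07, and 0.182 with estimated correlation). Glucocorticoid-responsive genes rose in 1 of 14, Angptl4 (camera adjusted p = 7.17e-10, and 0.182 with estimated correlation). Adjusted over the list alone, 4 and 7 of these passed. Of 17098 features 109 changed, 24 higher and 85 lower. Run as a block gave 370, slide as a block 53, and run 1 alone 255. The count was 60, 38, 17 or 52 without saline rat 1, 2, 3 or 4, and 236 or 192 without AMPH 1 day rat 7 or 9.

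At 1 day after hyperthermia limma called 0 of 17098 MAV features against saline, with 1210 at an unadjusted p under 0.05. As a group, the 12 neuron markers had a median of 0.81 (camera adjusted p = 3.74e-14, and 0.0721 with estimated correlation), and 8 of them passed when adjusted over the list alone. Oligodendrocyte markers had a median of 0.22 (camera adjusted p = 0.0132, and 0.579 with estimated correlation), erythroid markers -0.82 (camera adjusted p = 0.0116, and 0.4 with estimated correlation) and interferon-responsive genes -0.40 (camera adjusted p = 5.16e-07, and 0.197 with estimated correlation). Amphetamine against hyperthermia at 1 day gave 0 calls by limma too, with 2012 at an unadjusted p under 0.05. There the neuron markers had a median of -0.82 (camera adjusted p = 7.18e-10, and 0.27 with estimated correlation, 9 adjusted over the list alone) and the glucocorticoid-responsive genes 0.49 (camera adjusted p = 2.17e-05, and 0.724 with estimated correlation, 4 adjusted over the list alone). The counts were 3 and 0 blocked by run, 0 and 0 by slide, and 0 and 1 within run 1. Against saline the count was 129 without EIH 1 day rat 23, and against amphetamine 309 or 42 without EIH 1 day rat 23 or 25, and 1 without AMPH 1 day rat 19.

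In the striatum amphetamine raised the whole set of heat shock genes at 3 h. Hspa1a was 159-fold higher than in saline rats (log2 7.31 ± 0.54, adjusted p = 7.16e-10), from a level of -1.22 ± 0.09 (SD, n = 4), where 1 of 4 saline arrays lay above background, to 6.09 ± 0.68 (SD, n = 7). Hspb1 was 31.8-fold higher, Hmox1 16-fold, the transcription factor gene Atf3, not above background in saline rats, at least 13.4-fold, the co-chaperone gene Bag3 13.6-fold, the collagen chaperone gene Serpinh1 7.77-fold, Hsph1 6.33-fold, Cebpd 6.12-fold, Fos 5.99-fold with 2 of 4 saline arrays above background, and Cacybp 5.09-fold. Lower were the smooth muscle phosphatase inhibitor gene Ppp1r14a (4.15-fold), Ddc, the aromatic amino acid decarboxylase (3.64-fold, adjusted p = 3.23e-05), the vessel transporter gene Slco1a4 (3.49-fold, adjusted p = 4.26e-05), Gng8 (3.26-fold), Prom1 (3.07-fold), Hsd3b2 (2.85-fold), the claudin gene Cldn5 (2.78-fold), Haghl (2.73-fold, 5 of 7 amphetamine arrays above background), Trem2 (2.7-fold) and Degs2 (2.69-fold, 1 of 7).

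All 19 heat shock and chaperone genes rose (camera adjusted p = 7.77e-31, and 0.00141 with estimated correlation), with Dnaja1 5.03-fold higher. Endoplasmic reticulum stress genes rose in 14 of 21 (camera adjusted p = 2.85e-10, and 0.00139 with estimated correlation), among them Hspa5 (2.5-fold) and Ddit3 (2.24-fold), the stress transcription factor CHOP. Of 22 immediate early genes 14 rose (camera adjusted p = 4.31e-11, and 0.11 with estimated correlation), with Egr4 4.3-fold and Nr4a3 3.88-fold higher. Glucocorticoid-responsive genes rose in 7 of 13 (camera adjusted p = 8.78e-05, and 0.195 with estimated correlation), with Tsc22d3 1.98-fold higher. Oxidative stress genes rose in 4 of 8 and fell in 1 (camera adjusted p = 0.032, and 0.11 with estimated correlation). Inflammatory genes rose in 2 of 7 (camera adjusted p = 0.0359, and 0.195 with estimated correlation). Endothelial markers fell in 6 of 11 (camera adjusted p = 0.0117, and 0.195 with estimated correlation). Tight junction and barrier transporter genes fell in 7 of 13 (camera adjusted p = 0.00662, and 0.136 with estimated correlation), with Abcg2 2.16-fold and Ocln 1.56-fold lower (1 and 2 of 7 amphetamine arrays above background). Leptomeningeal fibroblast markers fell as well, in 6 of 14 (camera adjusted p = 0.0117, and 0.455 with estimated correlation), among them Mgp (1.95-fold). When adjusted over the list alone, 19 heat shock, 17 endoplasmic reticulum, 18 immediate early, 8 glucocorticoid, 5 oxidative, 3 inflammatory, 6 endothelial, 7 barrier and 8 leptomeningeal genes passed. Of 16798 features 3598 changed, 1642 higher and 1956 lower. Allowing for run left 4898, allowing for slide 4798, and within run 2 it was 4541, where 4 amphetamine arrays meet the saline arrays.

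Hyperthermia at 3 h also raised heat shock genes in STR. Hspa1a was 177-fold higher (7.47 ± 0.61, adjusted p = 1.55e-08, 1 of 4 saline arrays above background and 1 of 4 hyperthermia arrays saturated, so not exact), Hspb1 12.1-fold, Hmox1 10.1-fold, Bag3 9.92-fold and Hsph1 6.24-fold. In all 17 of 19 heat shock genes rose (camera adjusted p = 2.48e-19, and 0.0162 with estimated correlation). Endoplasmic reticulum stress genes rose in 14 of 21 and fell in 2 (camera adjusted p = 2e-07, and 0.00853 with estimated correlation), with Hsp90b1 2.86-fold higher. Immediate early genes rose in 11 of 22 and fell in 2 (camera adjusted p = 0.000989, and 0.49 with estimated correlation). Interferon-responsive genes fell in 5 of 9 (camera adjusted p = 0.0253, and 0.49 with estimated correlation), with Oas1a 2.37-fold and Irf7 2.09-fold lower. Leptomeningeal markers fell in 5 of 14 (camera adjusted p = 0.0253, and 0.49 with estimated correlation). Hsd3b2 (6.41-fold), Aph1a (3.66-fold), Ppp1r14a (3.44-fold), Gng8 (3.26-fold) and Plekho2 (3.11-fold) were lowest. Past the threshold adjusted over the list alone were 18 heat shock, 18 endoplasmic reticulum, 15 immediate early, 5 interferon and 7 leptomeningeal genes.

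Of 16798 features 5153 passed, 2241 higher and 2912 lower, but here the 4 hyperthermia arrays lie in run 1 and the 4 saline arrays in run 2. Blocked by run, estimated from the other groups, 2671 passed (1520 higher), and 1516 of the 5153 kept their call and sign. Blocked by slide 2357 passed. The count was 3325 without EIH 3 h rat 12.

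Compared with hyperthermia at 3 h, amphetamine left Cebpd in STR 3.48-fold higher (1.80 ± 0.22, adjusted p = 3.14e-05), Adamts9 2.54-fold, Junb 2.51-fold and Fosl1 2.35-fold, the last with 6 of 7 and 2 of 4 arrays above background. P2ry12 was 2.03-fold lower, Lrrc4c 1.97-fold and Apln 1.77-fold. Inflammatory genes were higher in 3 of 7 (camera adjusted p = 0.00714, and 0.264 with estimated correlation, 4 adjusted over the list alone), namely Ccl2 (2.45-fold, 6 of 7 amphetamine and 2 of 4 hyperthermia arrays above background), Nfkbia (1.99-fold) and Icam1 (1.37-fold, 6 of 7 amphetamine arrays). Immediate early genes were higher in 4 of 22 (camera adjusted p = 0.00714, and 0.616 with estimated correlation, 8 adjusted over the list alone). Of 16798 features 421 differed, 196 higher after amphetamine. Blocked by run, 204 passed, blocked by slide 11, and within run 1 alone 100. The count was 71, 144 or 92 without EIH 3 h rat 12, 13 or 14, and 175, 218 or 186 without AMPH 3 h rat 5, 27 or 29.

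In STR at 1 day after amphetamine Hspb1 was 9.4-fold higher than in saline rats (3.23 ± 0.47, adjusted p = 2.93e-05), the calcium-binding protein gene S100a10 5.15-fold, Cebpd 5.09-fold, the galectin gene Lgals3 5.07-fold and Hmox1 4.96-fold. Ddc (3.11-fold, 7 of 8 amphetamine arrays above background), the Notch target gene Hes5 (3.04-fold), C19h1orf198 (2.58-fold), Fmod (2.39-fold) and Gng8 (2.35-fold) were lowest. Heat shock genes rose in 10 of 19 and fell in 1 (camera adjusted p = 7.38e-05, and 0.34 with estimated correlation). Oxidative stress genes rose in 4 of 8 (camera adjusted p = 0.00561, and 0.0463 with estimated correlation) with the peroxiredoxin gene Prdx1 1.83-fold and Mt1 3.57-fold higher. Glucocorticoid-responsive genes rose in 6 of 13 (camera adjusted p = 0.000194, and 0.32 with estimated correlation) with Sgk1 3.13-fold higher. Endoplasmic reticulum stress genes rose in 11 of 21 and fell in 1 (camera adjusted p = 0.000172, and 0.0463 with estimated correlation). Leptomeningeal markers fell in 8 of 14 (camera adjusted p = 0.00686, and 0.475 with estimated correlation). Erythroid markers fell in all 4 (camera adjusted p = 0.0132, and 0.431 with estimated correlation). Adjusted over the list alone, 11 heat shock, 5 oxidative, 9 glucocorticoid, 13 endoplasmic reticulum, 10 leptomeningeal and 4 erythroid genes passed. Of 16798 features 4200 changed, 1994 higher and 2206 lower. The run-blocked count was 4700, the slide-blocked one 4860 and that within run 2 was 5157. The count was 2741 without saline rat 2.

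Amphetamine against hyperthermia at 1 day is a comparison of matched times. In STR Hspb1 was 7.18-fold higher after amphetamine (2.84 ± 0.43, adjusted p = 0.000151), S100a10 4.74-fold, Cebpd 4.58-fold, Lgals3 4.48-fold and Timp1 4.42-fold, while Hes5 was 2.31-fold lower and Btbd17 2-fold. Microglia and macrophage markers were higher in 6 of 12 (camera adjusted p = 0.0121, and 0.406 with estimated correlation, 8 adjusted over the list alone), with the complement gene C1qb 1.93-fold and Aif1 1.63-fold higher. Inflammatory genes were higher in 4 of 7 (camera adjusted p = 0.000369, and 0.0655 with estimated correlation, 5 adjusted over the list alone), with the chemokine gene Ccl3 3.25-fold higher (1 of 5 hyperthermia arrays above background). Of 16798 features 1497 differed, 1086 higher after amphetamine. Run as a block gave 3772 (2001 higher and 1771 lower), slide as a block 2886 (1520 and 1366), and run 1 alone 437. The count was 775 without EIH 1 day rat 21, and 982 or 992 without AMPH 1 day rat 28 or 30.

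Hyperthermia at 1 day left smaller changes in STR. The transcription factor gene Lhx2 was 1.92-fold higher than in saline rats (0.94 ± 0.13, adjusted p = 0.000727) and Ccng1 1.79-fold, while Rasgrp2 was 2.37-fold lower, the plakophilin gene Pkp4 2.29-fold, the calreticulin gene Calr 2.13-fold and Alas2 1.86-fold. Leptomeningeal markers fell in 1 of 14, Crabp2 (camera adjusted p = 0.00138, and 0.652 with estimated correlation, 9 adjusted over the list alone). Erythroid markers fell in 1 of 4, Alas2 (camera adjusted p = 0.00936, and 0.652 with estimated correlation, 4 adjusted over the list alone). Of 16798 features 501 passed, 162 higher and 339 lower, but 4 of the 5 hyperthermia arrays lie in run 1. Blocked by run, 1160 passed, and by slide 963. The count was 178, 35, 84 or 212 without saline rat 1, 2, 3 or 4, and 309, 190, 129 or 3184 without EIH 1 day rat 21, 22, 23 or 25.

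In the parietal cortex amphetamine raised heat shock genes and the synaptic activity gene Arc at 3 h. Hspa1a was 81.6-fold higher than in saline rats (log2 6.35 ± 0.58, adjusted p = 4.54e-08), with levels of 5.29 ± 1.35 (SD, n = 7) and -1.06 ± 0.07 (SD, n = 4). Hspb1 was 26-fold higher, Arc 11.3-fold, Cebpd 9.85-fold, Hmox1 9.31-fold, Bag3 8.52-fold, Mt1 6.53-fold and Coq10b 5.13-fold. The chemokine gene Ccl2 and Atf3, not above background in saline rats, were at least 6.47-fold and at least 5.21-fold higher. Slco1a4 was 3.57-fold lower (-1.83 ± 0.27, adjusted p = 6.86e-05), Prom1 3.01-fold with 6 of 7 amphetamine arrays above background, Ddc 2.94-fold with 5 of 7, Ppp1r14a 2.67-fold, P2ry12 2.45-fold, the clock output gene Dbp 2.39-fold, Abcg2 2.37-fold with 2 of 7, Degs2 2.32-fold with 3 of 7, Septin4 2.26-fold and Kalrn 2.19-fold.

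Heat shock genes rose in 17 of 19 (camera adjusted p = 4.03e-22, and 0.0133 with estimated correlation). Endoplasmic reticulum stress genes rose in 14 of 21 (camera adjusted p = 4.31e-12, and 0.0129 with estimated correlation), with Ddit3 2.67-fold and Manf 2.18-fold higher. Of 20 immediate early genes 13 rose (camera adjusted p = 2.75e-10, and 0.0752 with estimated correlation). Glucocorticoid-responsive genes rose in 9 of 13 (camera adjusted p = 3.18e-06, and 0.0752 with estimated correlation). Inflammatory genes rose in 5 of 9 (camera adjusted p = 0.00322, and 0.0752 with estimated correlation). Tight junction and barrier transporter genes fell in 5 of 12 (camera adjusted p = 0.00146, and 0.0419 with estimated correlation), with Ocln 1.57-fold (4 of 7 amphetamine arrays above background) and Cldn11 1.5-fold lower. Interferon-responsive genes fell in 4 of 9 (camera adjusted p = 0.00106, and 0.0752 with estimated correlation). Dopamine and catecholamine genes fell in 3 of 4, namely Ddc and the monoamine oxidase genes Maoa (1.37-fold) and Maob (1.33-fold) (camera adjusted p = 0.00399, and 0.0515 with estimated correlation). Oligodendrocyte markers fell in 3 of 8 (camera adjusted p = 0.0303, and 0.152 with estimated correlation). When adjusted over the list alone, 18 heat shock, 15 endoplasmic reticulum, 16 immediate early, 11 glucocorticoid, 6 inflammatory, 5 barrier, 5 interferon, 3 catecholamine and 3 oligodendrocyte genes passed. Of 16093 features 2374 changed, 1143 higher and 1231 lower. Allowing for run left 2626, allowing for slide 2748, and within run 1 it was 2464. The count was 1544 or 1461 without saline rat 2 or 3.

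After hyperthermia at 3 h heat shock genes rose in PC as well. Hspa1a was 120-fold higher (6.90 ± 0.70, adjusted p = 3.73e-06), Hspb1 35.3-fold, Hmox1 16.1-fold, Bag3 12.8-fold and Atf3 at least 11.1-fold. Of 19 heat shock genes 16 rose (camera adjusted p = 4.85e-40, and 0.00107 with estimated correlation). Slco1a4 was 3.15-fold lower, Ddc 2.78-fold, Prom1 2.65-fold with 2 of 3 hyperthermia arrays above background, the oligodendrocyte gene Opalin 2.45-fold and the interferon regulatory factor gene Irf7 2.33-fold. Interferon-responsive genes fell in 3 of 9 (camera adjusted p = 3.37e-06, and 0.0288 with estimated correlation). Of 21 endoplasmic reticulum stress genes 2 rose (camera adjusted p = 8.47e-11, and 0.0113 with estimated correlation). Past the threshold adjusted over the list alone were 17 heat shock, 5 interferon and 11 endoplasmic reticulum genes. Of 16093 features 305 changed, 125 higher and 180 lower. Blocked by run, 797 passed, blocked by slide 748, and within run 1 alone 908. The count was 169, 127, 165 or 175 without saline rat 1, 2, 3 or 4, and 48, 55 or 520 without EIH 3 h rat 13, 14 or 24.

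Amphetamine and hyperthermia at 3 h differed in few features of PC. Coq10b (2.49-fold), the cyclic AMP response gene Crem (2.25-fold), the phosphatase genes Dusp5 (2.22-fold) and Ptp4a1 (2.06-fold) and the corticotropin-releasing hormone gene Crh (2.22-fold, 1.15 ± 0.19, adjusted p = 0.00801) were higher after amphetamine. Immediate early genes had a median of 0.56 (camera adjusted p = 3.65e-05, and 0.329 with estimated correlation, 6 adjusted over the list alone). All 18 features past the threshold, of 16093, were higher after amphetamine. The run-blocked count was 19, the slide-blocked one 2 and that within run 1 was 4. The count was 36 or 0 without EIH 3 h rat 13 or 24, and 29 without AMPH 3 h rat 5.

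By 1 day after amphetamine PC kept raised Hspb1, Mt1 and Cebpd. They were 6.93-fold (2.79 ± 0.59, adjusted p = 0.00511), 6.39-fold and 4.16-fold higher than in saline rats, with Timp1 3.09-fold and the cell cycle inhibitor gene Cdkn1a 3.07-fold higher. Ddc (2.76-fold, 7 of 8 amphetamine arrays above background), the NMDA receptor subunit gene Grin2a (2.5-fold), Sema7a (2.44-fold), Tril (2.43-fold) and Cml3 (2.39-fold, 7 of 8) were lower. Glucocorticoid-responsive genes rose in 6 of 13 (camera adjusted p = 1.19e-05, and 0.225 with estimated correlation) and heat shock genes in 4 of 19 (camera adjusted p = 0.00049, and 0.302 with estimated correlation). Microglia and macrophage markers rose in 2 of 12, the complement genes C1qb (2.3-fold) and C1qa (1.64-fold) (camera adjusted p = 0.0471, and 0.319 with estimated correlation). Neuron markers fell in 3 of 14 (camera adjusted p = 0.0479, and 0.225 with estimated correlation), among them Map2 (1.39-fold). Erythroid markers fell in 2 of 4 (camera adjusted p = 0.00595, and 0.302 with estimated correlation) and oligodendrocyte markers in 2 of 8 (camera adjusted p = 0.0471, and 0.302 with estimated correlation). Adjusted over the list alone, 7 glucocorticoid, 7 heat shock, 2 microglia, 3 neuron, 3 erythroid and 3 oligodendrocyte genes passed. Of 16093 features 1310 changed, 516 higher and 794 lower. Run as a block gave 894, slide as a block 585, and run 1 alone 261. The count was 503, 664, 607 or 670 without saline rat 1, 2, 3 or 4, and 867 or 791 without AMPH 1 day rat 19 or 28.

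Against hyperthermia at 1 day the cortex of amphetamine rats had more Fabp5, a fatty acid binding protein gene (2-fold, 1.00 ± 0.15, adjusted p = 0.00196), Lgals3 (2.13-fold), Fcrl2 (2.17-fold, 4 of 5 hyperthermia arrays above background), Ret (2.16-fold) and the adhesion receptor gene Cd44 (2.03-fold, 1 of 5), and less Gprc5b (1.49-fold) and Carmil1 (1.33-fold). Microglia and macrophage markers rose in 1 of 12, C1qb (1.96-fold) (camera adjusted p = 0.00143, and 0.387 with estimated correlation, 2 adjusted over the list alone). Of 16093 features 43 differed, 32 higher after amphetamine. Allowing for run left 67, allowing for slide 22, and within run 1 it was 2. The count was 17, 12 or 10 without EIH 1 day rat 11, 21 or 22, and 168, 166, 18, 18, 16 or 26 without AMPH 1 day rat 7, 9, 19, 20, 28 or 30. Hyperthermia at 1 day gave 0 calls by limma in PC against saline, with 935 at an unadjusted p under 0.05, and 9 without EIH 1 day rat 11, with 0 and 0 with run and slide as blocks and 0 within run 1. Its erythroid markers had a median of -0.43 (camera adjusted p = 0.000652, and 0.157 with estimated correlation) and its oligodendrocyte markers -0.34 (camera adjusted p = 0.000763, and 0.144 with estimated correlation).

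**Figure D1:**
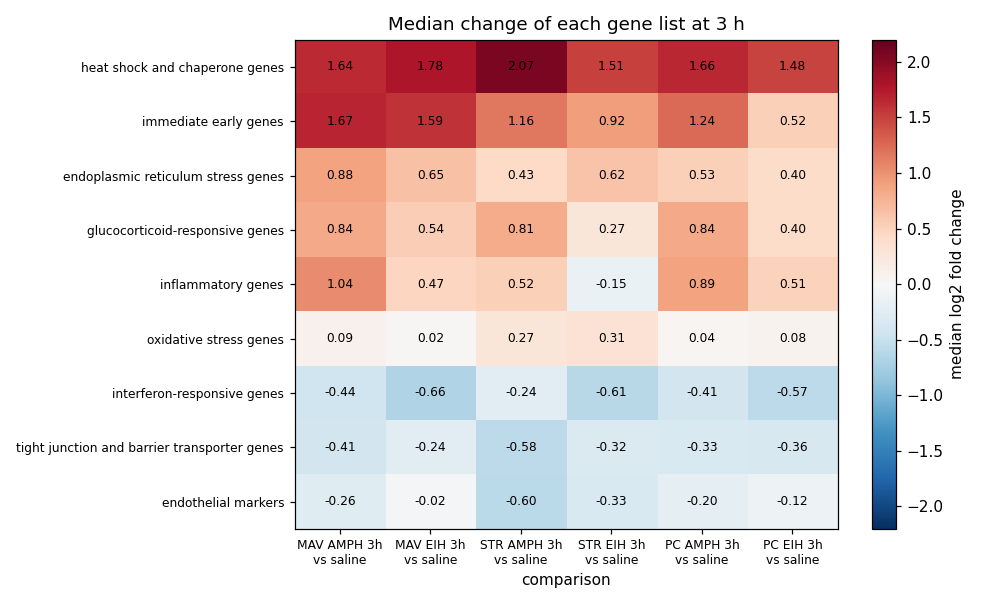
Median log2 fold change of 9 gene lists at 3 h against saline in each tissue, after amphetamine (AMPH) and hyperthermia (EIH). Each value is the median over the measured members of a list, and red marks a higher median. In STR the hyperthermia and saline arrays lie in different scan runs.

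Whether tissues answered amphetamine differently at 3 h was tested by the difference of their changes. In MAV the change of Fst exceeded that of STR by 3.22 ± 0.44 on the log2 scale (adjusted p = 2.65e-06) and that of PC by 2.51 ± 0.44. The changes of Reg3a, Reg3b, Has1 and Cxcl1 were larger in MAV too (adjusted p = 0.000431, 0.000692, 1.97e-05 and 7.92e-05 against STR). The sizes of these 4 are not exact, since after amphetamine the first 3 lay above background on no STR array and Cxcl1 on 2 of 7, and Reg3a and Reg3b on no MAV saline array. For Hspa1a the MAV minus STR difference was -3.34 ± 0.94 (adjusted p = 0.0171). Its size is not exact, with 1 of 7 MAV arrays saturated and 1 of 4 STR saline arrays above background. MAV saline levels (1.23 ± 2.45, SD) overlapped those after amphetamine. The difference was -2.07 ± 0.58 for the co-chaperone gene Bag3. For the transcription factor genes Klf5 and Klf10 it was -1.73 ± 0.29 and -1.68 ± 0.37. Against PC the lowest were the retinoic acid hydroxylase gene Cyp26b1 (-1.79 ± 0.39) and Klf10 (-1.76 ± 0.37). Inflammatory genes had the larger change in MAV in 4 of 18 against STR (camera adjusted p = 0.000645, and 0.562 with estimated correlation, 6 adjusted over the list alone) and in 4 against PC (camera adjusted p = 0.00429, and 0.74 with estimated correlation, 4 adjusted over the list alone), namely Cxcl1, Cxcl2, Il1rn and Socs3, none above background in STR saline rats. Against STR 1458 of 19303 features differed in their change and against PC 636, or 2851 and 1468 with the rat as a random block, and 1662 and 827 with run within tissue. The count against STR was 924 without STR saline rat 2, and against PC 418 or 354 without MAV saline rat 2 or 3, and 374, 369 or 358 without PC saline rat 2, 3 or 4, and 417 without PC AMPH 3 h rat 29.

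STR and PC differed in the change of 10 features. The neuropeptide gene Nts had the larger change in STR, by 1.38 ± 0.22 (adjusted p = 0.00049). The hormone gene Crh, the myelin gene Pmp22 and Selenom had the larger one in PC, with differences of -1.21 ± 0.22, -1.25 ± 0.24 and -0.87 ± 0.18, and the change of Gne, a gene of sialic acid synthesis, fell by 1.00 ± 0.20 from PC to STR. Nts lay above background on no PC array and Crh on no STR array of saline or amphetamine rats at 3 h, so these 2 sizes are not exact. With the rat as a random block 100 features passed, with run within tissue as a block 259, and the count was 4 or 5 without STR saline rat 2 or 3, and 20 without STR AMPH 3 h rat 26, and 2 or 3 without PC saline rat 3 or 4.

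**Figure D2:**
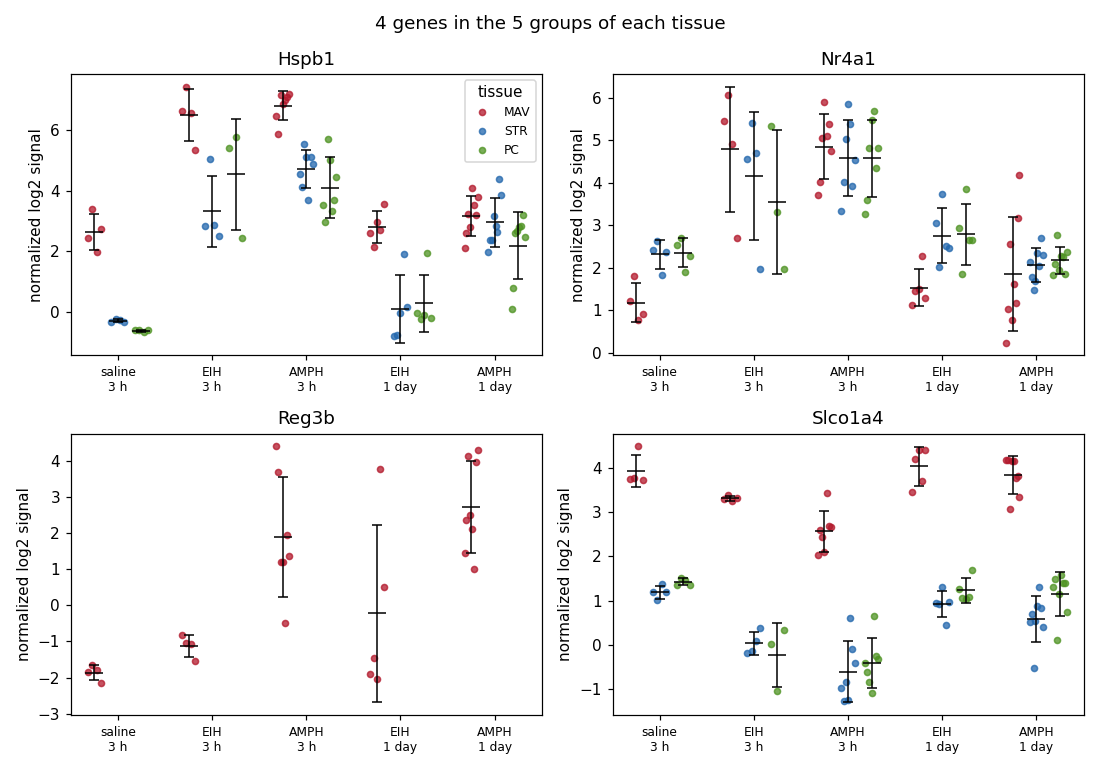
Normalized log2 signal of Hspb1, Nr4a1, Reg3b and Slco1a4 in each group of the 3 tissues. Points are arrays (rats), and bars the mean ± SD. Reg3b is shown for MAV alone. The time of each group is given below it.

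The last question is whether genes that mark the meninges respond to amphetamine. The 683 MAV-enriched features did not shift as a set between amphetamine and hyperthermia at 3 h. Their median was -0.05 against -0.01 for all features (camera p = 0.532, and p = 0.867 with an estimated correlation). At 1 day their median was 0.08 against 0.03 (camera p = 0.00696, and p = 0.47 with an estimated correlation), and with the background model fitted on every spot the direction turned (camera p = 0.0142). For amphetamine at 3 h against saline, set and change came from different pairs of saline rats. The median was below that of all features in all 6 pairs. It ran from -0.34 (set from rats 1 and 4) to -0.09 (rats 2 and 3). Camera p-values ran from 2.55e-09 to 0.0614, and from 0.109 to 0.607 with an estimated correlation. These tests miss opposite moves, and changed members were not counted. Among members, Hspb1 rose and Ocln and Slco1a4 fell.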

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

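The tests of heat exposure, of endothelial cell number and of heating in both exposures below were chosen after the result was seen, and run-blocked counts and list medians had been seen before the others.

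Among 193 groups of values of named genes, 9 held an array far from the others, and chance gives about 1 in 20 groups. The figures in brackets are the gap to the nearest array over the whole range. In MAV saline rats, rat 3 had the lowest Ttr (5.52 against a mean of 7.50, 0.953, with 3 of the 4 arrays saturated, which narrows their spread) and the highest Trem2 (3.18 against 2.59, 0.932). In PC saline rats, rat 3 had the lowest Rnf112 (4.48 against 4.80, 0.91), and in STR saline rats, rat 1 had the lowest Haghl (0.66 against 0.75, 0.881). After amphetamine at 3 h rat 26 stood apart in each tissue, with the highest Degs2 in MAV (0.36 against -1.12, 0.582). In STR it had the lowest Serpinh1 (3.50 against 4.47, 0.736) and the highest Ddc (0.90 against -0.75, 0.705), and in PC the lowest Mt1 (1.98 against 4.25, 0.576) and the highest Ddc (0.15 against -1.17, 0.613).

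The amphetamine change at 3 h differed in 1458 features between MAV and STR, 636 between MAV and PC and 10 between STR and PC. The log2 differences of MAV minus STR were 4.02 for Reg3a, 3.89 for Reg3b, 3.22 for Fst, 3.15 for Has1 and 2.68 for Cxcl1, and -3.34 for Hspa1a, -2.07 for Bag3, -1.73 for Klf5, -1.70 for C19h16orf87 and -1.68 for Klf10. For MAV minus PC they were 3.53 for Reg3b, 3.50 for Reg3a, 2.82 for Has1, 2.59 for Cxcl1 and 2.51 for Fst, and -1.79 for Cyp26b1, -1.76 for Klf10, -1.57 for Ccdc37, -1.46 for Pdgfrl and -1.43 for Ada. For STR minus PC they were 1.38 for Nts and 0.55 for Gnptg, and -1.25 for Pmp22, -1.21 for Crh and -0.87 for Selenom, and the change of Gne fell by 1.00 from PC to STR. The sizes are not exact for Hspa1a, as stated above, and for Reg3a, Reg3b, Has1, Cxcl1, Ccdc37, Pdgfrl, Ada, Nts, Gnptg and Crh. For the latter, 1 or more groups compared lay below background on most arrays.

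In STR the 5153 calls for hyperthermia at 3 h set 4 arrays of run 1 against 4 of run 2. The scan run may account for part of them: the run difference within the other STR groups correlated with this change at 0.64 over 16798 features, against -0.03 and 0.02 for the same change in MAV and PC, an excess of 0.63. Heat exposure may account for another part, since 19 of 19 heat shock genes rose with run as a block. With that block 1516 of the 5153 calls kept their side and sign. Which of the others follow the exposure stays open, since no STR saline array lies in run 1.

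In MAV the neuron markers had a median of 0.82 for hyperthermia over amphetamine at 1 day. Limma called 0 features there, and with estimated correlation the list did not pass. Adherent brain tissue is a candidate cause. The 409 genes at least 8-fold lower in MAV than PC had a median of 0.60 (72.8% of 0.82), against -0.03 for all features. Oligodendrocyte markers had a median of 0.42 and astrocyte markers 0.05. Only the listed neuron markers were left out of the 409 genes, so their shift does not tell adherent tissue from a change in neurons. A single array is argued against by the median over saline, 0.81 with all arrays and 0.59 without rat 21, though the markers were uneven, at 1.35 and 1.57 above the saline mean in rats 11 and 21 and -0.08 in rat 23. A change within the neurons or nerve fibres of the meninges was not tested.

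Slco1a4 was lower at 3 h after amphetamine in STR and PC. Fewer endothelial cells are argued against as the whole account, as 20 of 21 values of other endothelial markers (9 of 10 in STR, 11 of 11 in PC) lay above it by over 2 standard errors, although Slco1a4 was picked as among the lowest. A loss of these cells stays open for part of it, as 5 of the 10 others passed the threshold in STR, all lower, and 3 of the 11 in PC, 1 of them higher. A scan run difference is argued against by the run-blocked change, -1.55 in STR and -2.06 in PC (highest adjusted p 3.93e-05). Hyperthermia alone lowered Slco1a4 3.15-fold in PC. In STR, across runs, it was -0.18 to 0.39 against 1.01 to 1.37 in saline rats. Whether heating is the whole account stays open: amphetamine minus hyperthermia was -0.65 (interval -1.23 to -0.07) in STR and -0.18 (-0.80 to 0.44) in PC.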

How the results depend on the processing

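Run and slide as fixed blocks, fits within a run, the background versions, leaving out the doubtful arrays and run within tissue were chosen after the data were seen. Of 604 values for named genes none turned direction under another setting, and 595 kept their side of the threshold with quantile scaling, 596 with the deposited values, 602 with capped background, 405 with the model on all spots, 343 of 375 with run as a block, 300 of 375 with slide as a fixed block, 183 of 257 within run 1, 318 of 374 in fits on the 2 groups compared and 5912 of 6393 on leaving out 1 array. Of 169 list calls 157, 160, 164 and 144 were kept in the first 4 of these settings, and 101 of 127 with run as a block. Depth limits the dim probes: at the median array 46.62% of spots lay well above background. The cause of the moves below was not tested. They are set against the counts given with each comparison, and brackets give the higher calls where their share moved by over 10 points.

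With the background model fitted on all spots the counts were STR against PC 2825 (1341 higher), MAV AMPH 3 h 647, MAV EIH 3 h 67 (53 higher), MAV AMPH against EIH at 3 h 4 (4 higher), MAV AMPH 1 day 8, STR AMPH 3 h 469 (352 higher), STR EIH 3 h 1835 (1072 higher), STR AMPH against EIH at 3 h 2 (2 higher), STR AMPH against EIH at 1 day 268, STR AMPH 1 day 1389 (952 higher), STR EIH 1 day 0, PC AMPH 3 h 359, PC EIH 3 h 15 (13 higher), PC AMPH against EIH at 3 h 0, PC AMPH against EIH at 1 day 5 (5 higher), PC AMPH 1 day 87, the MAV minus STR difference 93 (27 higher), the MAV minus PC difference 11 (7 higher) and the STR minus PC difference 0. There the MAV-enriched set under amphetamine at 1 day turned from Up to Down (0.0142 by camera, from 0.00696), and the set from saline rats 2 and 3 passed (6.5e-08, from 0.0614). With no filter on dim probes, which tests more probes, they were MAV against STR 30058 (6511 higher), MAV against PC 18655 (7500 higher), STR against PC 22508 (18953 higher), MAV EIH 3 h 322, MAV AMPH against EIH at 3 h 17 (12 higher), MAV AMPH 1 day 72, STR AMPH 3 h 2326, STR EIH 3 h 6109 (1810 higher), STR AMPH against EIH at 3 h 88, STR AMPH against EIH at 1 day 598, STR EIH 1 day 40, PC AMPH against EIH at 1 day 19, the MAV minus STR difference 943 and the MAV minus PC difference 328.

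With quantile scaling they were MAV AMPH against EIH at 3 h 121, MAV AMPH 1 day 144 (47 higher), STR EIH 1 day 1084 (510 higher), PC AMPH against EIH at 1 day 47 (30 higher) and the STR minus PC difference 35, and the set from saline rats 2 and 3 passed (0.0335). With the deposited values the counts were MAV AMPH against EIH at 3 h 83 (59 higher), STR AMPH against EIH at 1 day 1281 (721 higher), STR EIH 1 day 824 (398 higher), PC EIH 3 h 236 (128 higher) and the STR minus PC difference 23. With the mean of probes PC EIH 1 day 1.

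With slide as a random block the counts were MAV EIH 3 h 882, STR EIH 3 h 3297 (1838 higher), STR AMPH against EIH at 1 day 2528, PC EIH 3 h 877, PC AMPH against EIH at 1 day 181 (90 higher), PC EIH 1 day 7 and the STR minus PC difference 31. With slide as a fixed block they were MAV EIH 3 h 759, MAV AMPH against EIH at 3 h 10, MAV AMPH 1 day 53, STR EIH 3 h 2357 (1292 higher), STR AMPH against EIH at 3 h 11 (7 higher), STR AMPH against EIH at 1 day 2886 (1520 higher), STR EIH 1 day 963 (215 higher), PC EIH 3 h 748, PC AMPH against EIH at 3 h 2, PC AMPH against EIH at 1 day 22 (14 higher) and PC AMPH 1 day 585. With run as a block they were MAV AMPH 3 h 2950 (915 higher), MAV EIH 3 h 817, MAV AMPH against EIH at 3 h 98 (42 higher), MAV AMPH 1 day 370, MAV EIH 1 day 3, STR EIH 3 h 2671 (1520 higher), STR AMPH against EIH at 3 h 204, STR AMPH against EIH at 1 day 3772 (2001 higher), STR EIH 1 day 1160, PC EIH 3 h 797 and PC AMPH against EIH at 1 day 67 (36 higher). Within run 1 they were MAV AMPH 3 h 1550, MAV AMPH against EIH at 3 h 15 (12 higher), MAV AMPH against EIH at 1 day 1, MAV AMPH 1 day 255, STR AMPH against EIH at 3 h 100 (58 higher), STR AMPH against EIH at 1 day 437, PC EIH 3 h 908 (277 higher), PC AMPH against EIH at 3 h 4, PC AMPH against EIH at 1 day 2 (2 higher) and PC AMPH 1 day 261 (73 higher).

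In fits on the 2 groups compared, which estimate the spread from fewer arrays, they were MAV AMPH against EIH at 3 h 2 (2 higher), MAV AMPH 1 day 14 (6 higher), STR EIH 3 h 9458, STR AMPH against EIH at 3 h 770, STR AMPH against EIH at 1 day 277 (232 higher), STR EIH 1 day 30 (4 higher), PC EIH 3 h 1046 (239 higher), PC AMPH against EIH at 3 h 0, PC AMPH against EIH at 1 day 15 (14 higher) and PC AMPH 1 day 694. Without the 3 doubtful arrays they were MAV AMPH against EIH at 3 h 144, MAV AMPH 1 day 236 (97 higher), STR AMPH against EIH at 1 day 775 (435 higher), STR EIH 1 day 309 (176 higher), PC AMPH against EIH at 1 day 26 (22 higher) and the STR minus PC difference 39. A fit over all 83 arrays gave STR against PC 4219, or 3902 (1553 higher) with run as a block. With run within tissue the count was the MAV minus STR difference 1662 (605 higher) and the STR minus PC difference 259 (73 higher). A minimum log2 difference of 1 gave 2033 MAV-enriched features and one of 3 gave 239.

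With the rat as a random block, for the pairing of tissues, the counts were the MAV minus STR difference 2851, the MAV minus PC difference 1468 and the STR minus PC difference 100. With the rat as a fixed block the saline comparisons gave 14042 for MAV against STR, 14425 for MAV against PC and 8494 for STR against PC, and the block changed no other call of a comparison. Within a tissue each rat has 1 array, so no paired analysis was possible there. Slide as a block could not be fitted to the saline arrays, since slides held 1 tissue.

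Leaving out 1 array in turn gave 13318 to 13876 for MAV against STR, 13776 to 14258 for MAV against PC, 667 to 718 for MAV-enriched features, 6618 to 8246 for STR against PC, 1642 to 2758 for MAV AMPH 3 h, 112 to 1054 for MAV EIH 3 h, 17 to 236 for MAV AMPH 1 day, 0 to 129 for MAV EIH 1 day, 10 to 309 for MAV AMPH against EIH at 3 h, 0 to 309 for MAV AMPH against EIH at 1 day, 2512 to 4003 for STR AMPH 3 h, 3325 to 4686 for STR EIH 3 h, 2741 to 4880 for STR AMPH 1 day, 35 to 3184 for STR EIH 1 day, 71 to 604 for STR AMPH against EIH at 3 h, 775 to 1809 for STR AMPH against EIH at 1 day, 1461 to 2749 for PC AMPH 3 h, 48 to 520 for PC EIH 3 h, 503 to 1947 for PC AMPH 1 day, 0 to 9 for PC EIH 1 day, 0 to 36 for PC AMPH against EIH at 3 h, 10 to 168 for PC AMPH against EIH at 1 day, 924 to 1765 for the MAV minus STR difference, 354 to 772 for the MAV minus PC difference, 2 to 20 for the STR minus PC difference.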

Other observations

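The splits in this part were chosen after the results were seen, the list tests before.

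Vasoactive genes, of receptors and peptides that set vessel width, were higher in MAV than in STR in 9 of 16 and lower in 5 (camera adjusted p = 0.0431, and 0.422 with estimated correlation), and higher than in PC in 10 and lower in 3 (camera adjusted p = 0.0284, and 0.368 with estimated correlation), with 14 and 13 past the threshold adjusted over the list alone. Astrocyte markers were higher in 3 of 8 and lower in 4 against STR (camera adjusted p = 0.93, and 0.949 with estimated correlation, 7 adjusted over the list alone). Circadian clock genes had a median of 0.19 in MAV after hyperthermia at 3 h (camera adjusted p = 0.0406, and 0.304 with estimated correlation), with 4 of 13 past the threshold adjusted over the list alone.

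The arrays of each comparison were also split into mixed groups of the same sizes. Brackets give the real count, the highest among the other splits and, in places, the number of splits as large, the real one included. Shares of splits are unadjusted over tests. No other of 35 splits was as large for MAV against STR (13832 against 0) and against PC (14225 against 0). The same held for STR against PC (8196 against 1). Among the 8 splits that part every pair of tissues of a rat the highest other was 0. Mixing tissues hides their differences, so these splits test little. No other of 35 was as large for EIH 3 h in MAV (492 against 72), STR (5153 against 0) and PC (305 against 1). In STR EIH 3 h, and by run labels in STR against MAV and PC, the real split itself follows the scan runs. No other of 100 was as large for AMPH 3 h in MAV (2611 against 69), STR (3598 against 1487) and PC (2374 against 1062). The same held for STR AMPH against EIH at 3 h (421 against 211) and STR AMPH 1 day (4200 against 2744). It held for the MAV minus STR (1458 against 111), MAV minus PC (636 against 95) and STR minus PC (10 against 5) differences. The last gave 0 with the background model on all spots, and 2 to 20 on leaving out 1 array. It also held for MAV-enriched features (683 against 0), which mix tissues too. For MAV AMPH against EIH at 3 h (62 against 136, 3 of 100) the highest split called over 2 times the real count. Its count was 10 with slide as a block, 15 within run 1 and 2 in a fit on the 2 groups.

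For STR EIH 1 day (501 against 4414, 2 of 100) and PC AMPH 1 day (1310 against 5774, 2 of 100) few splits were as large, but in both the highest split follows the scan runs and calls several times the real count, which points to a structure of the arrays. In STR EIH 1 day the real split nearly follows the runs too, with 4 of 5 hyperthermia arrays in run 1 and all 4 saline arrays in run 2, so the splits do not speak for the exposure there. The run-blocked counts are 1160 and 894. MAV EIH, MAV AMPH against EIH and PC EIH at 1 day had a real count of 0 (highest others 184, 104 and 10). All 100 splits are then as large, so they decide nothing. Chance cannot be excluded by these splits for MAV AMPH 1 day (109 against 1304, 8 of 100), STR AMPH against EIH at 1 day (1497 against 4080, 7 of 100), PC AMPH against EIH at 3 h (18 against 1040, 8 of 100) and PC AMPH against EIH at 1 day (43 against 2591, 6 of 100), and in several of them a split called several times the real count. The splits do not hold the run fixed: in STR and PC AMPH against EIH at 1 day the groups of the highest split differed more in run 2 share than the real ones (0.675 against 0.3 in both). Run-blocked counts, 3772 and 67, may be too high and do not test chance. For the list tests by camera for amphetamine at 3 h, 11 of 100 splits gave as many calls as the real 27 (highest other 32), so chance cannot be excluded. For the MAV-enriched set between amphetamine and hyperthermia, 85 of 100 splits gave as low a camera p as 0.532 at 3 h (lowest other 3.78e-09) and 42 of 100 as 0.00696 at 1 day (lowest other 8.69e-12), so chance cannot be excluded in either.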
